A study of Homo sapiens with 14 samples.

How the data were processed

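RNA-seq was measured in HUDEP-2 cells, an immortalised human erythroid progenitor line, on day 5 of erythroid differentiation. The cells expressed Cas9 and received a control guide RNA (2 libraries), guides against NFIA (4 libraries), guides against NFIX (4 libraries) or guides against both genes (4 libraries). Each of the 3 knockout groups held 2 guides or guide sets with 2 replicates each, so the 14 libraries formed 4 groups. The groups are called NFIA knockout, NFIX knockout and double knockout after their labels, which give no editing rate and no protein level.

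Per the labels, about 200 ng of RNA was depleted of ribosomal and globin RNA, made into stranded total RNA libraries with 13 PCR cycles and read as 2 x 76 bp pairs. The authors aligned the reads to the human genome (hg38) with STAR and the GENCODE 29 gene set and quantified genes with RSEM, tool versions not stated. The deposited files hold 2 units per gene. The deposited expected counts are RSEM's fragment counts without normalisation, of which 5.0% on average were not whole numbers. The deposited TPM values are length-scaled shares of all annotated genes, small structural RNAs included. Each library had its own file. The tables held 58721 genes and 92 rows for ERCC spike-in sequences, whose counts were all 0.

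Totals were 49388649 to 62548570 expected counts per library. Small structural RNAs took 36.26 to 49.71% of the counts and globin genes 10.66 to 13.8%. Counts of PCR-amplified fragments without molecular identifiers are not independent molecules, so intervals and count limits cover counting error only. A count of 0 allowed at most 0.061 CPM (3 counts) in the smallest library. Gene symbols, positions, GC content and transcript lengths came from GENCODE 44 (GRCh38). Of the gene identifiers 58252 were found in it and 41976 carried a symbol.

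Expected counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr by treatment (minimum count 10), glmQLFit and glmQLFTest in 1 fit of all 14 libraries with 1 coefficient per treatment. The fit had 10 residual degrees of freedom and tested 14906 genes. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Levels are CPM (counts scaled by TMM library sizes), as mean ± SD. Log2 fold changes carry approximate standard errors, the absolute log2 fold change over the square root of the test's F statistic. The comparisons were each knockout group against control, the 3 comparisons between knockout groups, and a non-additivity term, the double knockout effect minus the sum of both single effects. Guides were compared within each knockout group in a fit with 1 coefficient per treatment and guide.

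The gamma-globin share was the sum of HBG1 and HBG2 as a percentage of HBE1, HBG1, HBG2, HBD and HBB counts, compared with a two-sided exact permutation test. Between 4 knockout and 2 control libraries there are 15 splits, so the smallest possible p is 0.067 and 0.05 cannot be reached. Single-library shares carry 95% Wilson intervals. Because globin RNA was depleted, the share describes the counts left after depletion and does not measure the share in the cells.

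The 28 gene lists fixed in advance covered the NFI family, the beta-like and alpha-like globin clusters, fetal globin regulators, an oncofetal let-7 axis, adult-stage erythroid markers, erythroid transcription factors, heme synthesis and iron, red cell membrane and skeleton, late erythroid maturation, and erythroid progenitor genes. Other blood lineages were covered by megakaryocyte, neutrophil and monocyte, mast cell, basophil and eosinophil, and lymphoid lists. The rest covered S phase, G2 and M phase, replication-dependent histones, p53 targets, the integrated stress response, interferon-stimulated genes, cholesterol synthesis, hypoxia and glycolysis, heat shock proteins, immediate early genes, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, and nuclear RNAs as a sign of RNA quality. Lists with at least 4 tested members were tested with camera from limma 3.58.1 (preset correlation 0.01, two-sided, adjusted over the 26 lists tested), with an estimated correlation and fry beside it. No lymphoid gene was tested, and 3 NFI genes are described singly.

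Choices made before the data were examined were the tests, gene lists, gene naming rule and first set of alternatives. The naming rule took NFIA, NFIX, NFIB, NFIC and the globin genes in each comparison with control. It then took up to 10 of the largest rises and 10 of the largest falls per comparison with control among called genes with a mean of at least 1 CPM, a symbol that is not a clone, antisense or noncoding placeholder name, and all 4 knockout libraries on the same side of both controls. Comparisons between knockouts and the non-additivity term took up to 5 in each direction, each list up to 4 members with the smallest p, and each guide comparison 3 genes. The globin and NFI genes in comparisons between knockouts, and any gene said to be chosen after its values were seen, lie outside the rule. Some genes that the rule named are not reported here.

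Alternatives chosen at that stage were a replicate block, a guide-level fit, a fit of only the groups compared, DESeq2 1.42.0, edgeR's RLE size factors, globin genes removed before normalisation, no filter on low counts, each guide alone, limma-voom with the guide as a correlated block (estimated correlation -0.17), each library left out in turn, and TPM or another denominator for the gamma-globin share. Added after seeing the data were an offset that removed each library's spline trend (5 degrees of freedom) against GC content and transcript length, that offset with the replicate block, removal of small structural RNAs, omission of control replicate 1 and double knockout guide 1 replicate 2 together, and a gamma-globin share that counts a read-through gene. The trend was fitted on tested genes with known GC content and a mean log2 CPM above 1. It was applied to the 99.3% of tested genes with known GC content, and the others were tested without it.

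The numbers 1 and 2 of the replicates were checked as possible pairs. Over 21 pairs of group differences between replicate 1 and replicate 2, correlations across 6305 genes ran from -0.31 to 0.39, with 11 above 0.1, and 10 of 14 libraries matched their own number best. The numbers were not taken to pair the samples, and a replicate block was run as an alternative. The shared controls were allowed for in part by 20 simulations of unchanged groups against the same controls, with the same spread per gene in all groups. On simulated data with 50 changed genes per size, edgeR called 80% of 2-fold changes in NFIA knockout against control, with 5 false calls among 177. It called 62% in the non-additivity term. These data had the same spread per gene in all groups and no GC trend. The real controls differed in both, so these rates need not hold for comparisons with control. A simulated GC trend in 1 library gave a correlation of -0.49 between fold change and GC content, which was 0 with the offset. In that simulation 0 genes were called with or without the offset. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.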

Results

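Gene expression was measured by RNA-seq in 14 libraries of HUDEP-2 erythroid cells on day 5 of differentiation, to ask how loss of the NFI transcription factors NFIA and NFIX changes fetal globin and other RNAs in adult-type erythroid cells. Control guide cells gave 2 libraries and the NFIA, NFIX and double knockout groups 4 each. Library totals were 51392791 and 62548570 expected counts in control, 51328901 to 53976143 in NFIA knockout, 49388649 to 55617903 in NFIX knockout and 50978473 to 55951361 in double knockout. Control replicate 1 stood apart. Its deviation from the mean of all libraries correlated with GC content across genes (Spearman's rho 0.73, genes not being independent replicates, against -0.59 to 0.26 in the 12 knockout libraries), and its protein-coding share was 46.64% against 56.36% in control replicate 2. The counts of called genes against control are therefore also given without it, where the remaining control library is assumed to vary like the other groups.

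The targeted genes themselves were lower in RNA, though not in every group that received their guides. NFIA (ENSG00000162599, chromosome 1, 60865259 to 61462788, GRCh38) measured 159 CPM ± 42.9 (SD, n = 2) in control, 78.4 ± 16.6 (n = 4) in NFIA knockout, 189 ± 5.4 (n = 4) in NFIX knockout and 75.4 ± 21.3 (n = 4) in double knockout. It fell in NFIA knockout (log2 fold change -1.02 ± 0.21, adjusted p = 5.48e-03) and in double knockout (-1.08 ± 0.21, adjusted p = 1.11e-03), below both controls in 4 of 4 libraries each. It did not pass the test in NFIX knockout (0.25 ± 0.22, adjusted p = 0.546). NFIX (ENSG00000008441, chromosome 19, 12995475 to 13098796) measured 221 CPM ± 28.8 (n = 2) in control, 226 ± 8.26 (n = 4) in NFIA knockout, 155 ± 8.36 (n = 4) in NFIX knockout and 198 ± 7.21 (n = 4) in double knockout. It fell in NFIX knockout (-0.52 ± 0.09, adjusted p = 0.0243), but in double knockout it did not pass the test against control (-0.16 ± 0.09, adjusted p = 0.255) and was higher than in NFIX knockout (0.36 ± 0.08, adjusted p = 4.01e-03). The NFIX fall in NFIX knockout was -0.38 without control replicate 1, with an adjusted p of 0.233. That call was also lost without guide 1 replicate 1 (adjusted p = 0.0725), guide 1 replicate 2 (0.0504) or guide 2 replicate 1 (0.0597), and in double knockout NFIX was called lower without control replicate 2 (-0.28, adjusted p = 0.0356). NFIC, another family member, fell in NFIA knockout (-0.78 ± 0.22, adjusted p = 0.0289) and double knockout (-0.79 ± 0.22, adjusted p = 0.0148), and neither call held without control replicate 1 (adjusted p = 0.330 and 0.171), nor did the first without NFIA knockout guide 1 replicate 1 (0.0626). NFIB had 0 to 8 counts per library and was not tested. RNA levels of edited genes do not measure the loss of their proteins.

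**Figure D1:**
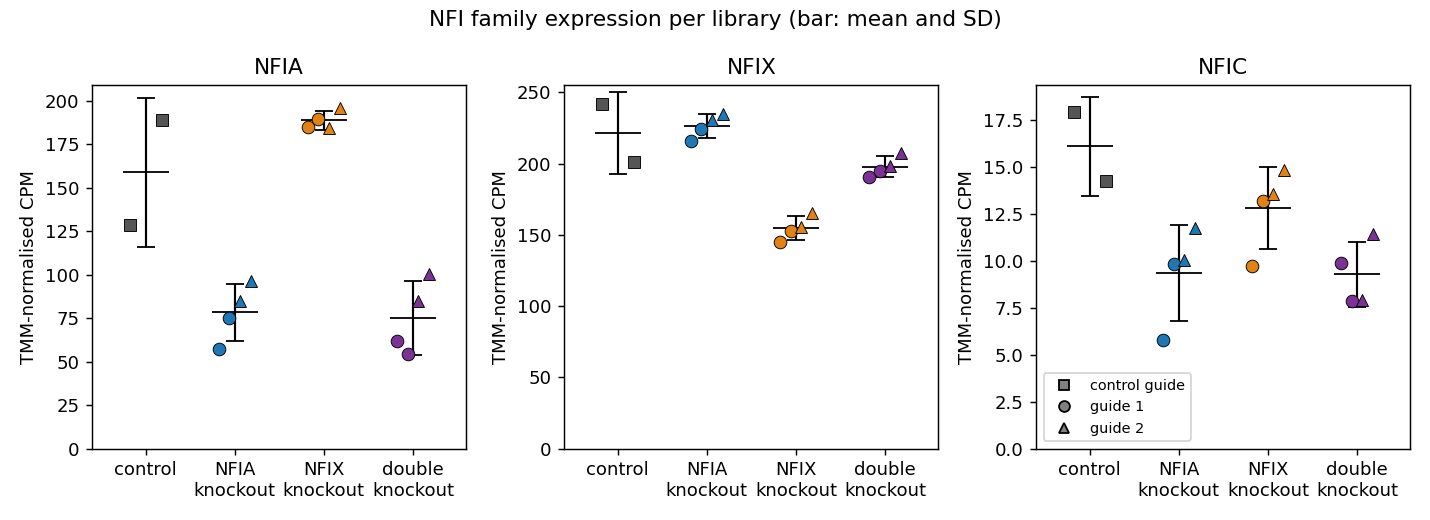
NFIA, NFIX and NFIC levels in TMM-normalised CPM for each library, with squares for control, circles for guide 1, triangles for guide 2, and the mean and SD per group. NFIA averaged 78.4 CPM in NFIA knockout and 75.4 in double knockout against 159 in control, and NFIX averaged 155 in NFIX knockout but 198 in double knockout against 221 in control.

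Fetal and embryonic globin RNA rose after NFIA knockout. HBG2, a fetal gamma-globin gene (ENSG00000196565, chromosome 11, 5253188 to 5505605), went from 166 CPM ± 26.9 (n = 2) to 630 ± 49.9 (n = 4), a 3.80-fold rise, and HBG1 (ENSG00000213934, chromosome 11, 5248269 to 5249857), its neighbour and near-copy, from 2.54 ± 0.617 to 14.8 ± 2.22. Embryonic HBE1 (ENSG00000213931, chromosome 11, 5268345 to 5505652) reached 2.14 CPM ± 0.374 from 0.112 ± 0.107, with 9 and 2 counts in the controls, and embryonic alpha-like HBZ (ENSG00000130656, chromosome 16, 142728 to 154503) went from 2.94 ± 0.678 to 7.74 ± 1.01. Adult HBB had 58700 CPM ± 4130 against 60600 ± 17500 in control and did not pass the test, nor did HBD, HBA1, HBA2, HBM and HBQ1. Without control replicate 2, HBB (-0.31, adjusted p = 0.0333), HBD (-0.42, 8.53e-03) and HBA1 (-0.51, 8.72e-03) were called lower. The gamma-globin share of the beta-like globin counts left after depletion was 1.06% ± 0.051 (SD, n = 4) against 0.276% ± 0.0374 (n = 2) in control.

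In the test against control the log2 fold changes were 1.93 ± 0.27 for HBG2 (adjusted p = 2.85e-04), 2.54 ± 0.34 for HBG1 (adjusted p = 2.12e-04), 4.27 ± 0.44 for HBE1 (adjusted p = 2.13e-05) and 1.40 ± 0.19 for HBZ (adjusted p = 2.50e-04), each above both controls in 4 of 4 libraries. BGLT3, a noncoding RNA of the beta-like cluster, also rose (1.96 ± 0.53, adjusted p = 0.0247), a call that was lost without control replicate 1 (adjusted p = 0.0698), control replicate 2 (0.114) or guide 1 replicate 1 (0.0651). HBBP1 did not pass the test (0.45 ± 0.15, adjusted p = 0.0617). As a list, the beta-like cluster moved up (adjusted p = 1.6e-07; adjusted p = 0.064 with an estimated correlation), with 4 of 7 members risen, 5 adjusted over the list alone. The share difference of 0.786 percentage points gave p = 0.067 in the exact permutation test, the smallest this design allows. The control shares were 0.249% (95% Wilson interval 0.244 to 0.254) and 0.302% (0.296 to 0.309). With the read-through gene ENSG00000284931, which spans HBG1 and HBG2, counted as gamma-globin, the difference was 1.88 points (2.46% against 0.587%), and from TPM it was 0.644 points. In control replicate 1 RSEM assigned 101 counts to HBG1, 8861 to HBG2 and 11062 to the read-through gene, which shares exon sequence with both. Separate HBG1 and HBG2 levels depend on that assignment.

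Among other named genes of NFIA knockout, SLC28A3, a nucleoside transporter (log2 fold change 4.43 ± 0.59), the chemokine receptor CCR4 (3.96 ± 0.63), CYRIA (3.24 ± 0.36), HMCN1 (3.06 ± 0.37), the fetal growth factor IGF2 (3.03 ± 0.35), the desmosomal gene DSP (2.85 ± 0.54), the cytokine IL18 (2.70 ± 0.29) and SH3BGRL2 (2.70 ± 0.37) rose most. They rose from control means of 0.0567 to 0.713 CPM. SERF1B rose as well (3.40 ± 0.69), with the limit that its copy SERF1A is nearly identical in sequence. The largest falls were in HR, a transcriptional corepressor (-2.84 ± 0.55), JAKMIP1 (-2.31 ± 0.34), PRX (-2.17 ± 0.29), ALOX5 of leukotriene synthesis (-2.06 ± 0.42), the immune checkpoint gene VSIR (-2.0 ± 0.22), SLC22A16 (-1.95 ± 0.43), GPT (-1.93 ± 0.25), TMSB10 (-1.90 ± 0.26), CAVIN1 (-1.89 ± 0.32) and GCNT2 (-1.91 ± 0.41), which makes the branched adult I antigen of red cells. The calls of DSP, HR, ALOX5 and SLC22A16 were lost without control replicate 1 (adjusted p = 0.0647, 0.0992, 0.145 and 0.0552).

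Late erythroid maturation genes included 11 rises and 2 falls of 36 tested (12 and 3 adjusted over the list alone), among them BPGM, which makes the oxygen-affinity regulator 2,3-bisphosphoglycerate (0.81 ± 0.13), and the carbonic anhydrases CA2 (0.79 ± 0.13) and CA1 (0.60 ± 0.11). The list itself was not called (adjusted p = 0.14). S phase genes moved up (8 rose and 1 fell of 29, 11 and 2 adjusted over the list alone; adjusted p = 4.8e-03, adjusted p = 0.60 with an estimated correlation), with CCNE2, a cyclin of S phase entry, at 0.81 ± 0.16 (no longer called without control replicate 1, adjusted p = 0.107). Mitochondrially encoded mRNAs moved down (10 of 13 fell, 13 adjusted over the list alone; adjusted p = 3.9e-11, adjusted p = 0.57 with an estimated correlation), MT-ND1 by -1.23 ± 0.22. Without control replicate 1 their median went from -0.98 to -0.36 (adjusted p = 5.5e-04), and MT-ND1 was at -0.59 and no longer called (adjusted p = 0.181). Replication-dependent histones moved down (9 of 24 fell, 15 adjusted over the list alone; adjusted p = 5.5e-08, adjusted p = 0.60 with an estimated correlation), with H1-3 at -0.58 ± 0.12 (adjusted p = 0.247 without control replicate 1). The call of the list was lost without control replicate 1 (adjusted p = 0.14) and with the GC and length trend removed (adjusted p = 0.35). Cytosolic ribosomal proteins moved down (3 of 79 fell, 1 adjusted over the list alone; adjusted p = 8.7e-03, adjusted p = 0.80 with an estimated correlation), and without control replicate 1 their direction turned to up (adjusted p = 0.77), and the call was lost without guide 2 replicate 2 (0.082). Immediate early genes moved down (2 of 15 fell, also 2 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.60 with an estimated correlation; adjusted p = 0.82 without control replicate 1 and 0.088 without guide 2 replicate 2), with IER3 at -1.21 ± 0.16. The other 20 lists tested were not called (adjusted p 0.13 to 1). With fry the calls of histones (adjusted p = 0.081), ribosomal proteins (0.41) and immediate early genes (0.1) were lost. Fry called the let-7 (0.011) and heme and iron (0.011) lists up. With the GC and length trend removed, the alpha-like (3.4e-06), heme and iron (0.022) and late maturation (0.02) lists were called up. Immediate early genes were then not called (0.35). The omission of control replicate 1 brought calls up for the alpha-like cluster (adjusted p = 5.5e-04), heme and iron (8.5e-03), late maturation (1.4e-03) and hypoxia and glycolysis (0.024). It brought a call down for interferon-stimulated genes (5.5e-04), and the omission of control replicate 2 a call up for G2 and M phase genes (1.8e-03). Median, mean and test differed in sign for the let-7, membrane, early erythroid, p53, integrated stress response, hypoxia, heat shock and nuclear RNA lists. Camera called none of them with all libraries.

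NFIA knockout changed 1576 of 14906 genes against control, 857 higher and 719 lower. The count was 304 without control replicate 1, and 256 of the 1576 kept their call. Without control replicate 2 it was 3960, and without guide 1 replicate 1 it was 782. With the GC and length trend removed it was 961. Of the 82 named genes called here, 52 lost the call without control replicate 1.

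Few genes were called between NFIX knockout and control with all libraries, a count that depended strongly on the control library, and the gamma-globin genes did not pass the test. HBG2 measured 227 CPM ± 92.9 (n = 4) against 166 ± 26.9 (n = 2; log2 fold change 0.46 ± 0.25, adjusted p = 0.327) and HBG1 5.45 ± 2.77 against 2.54 ± 0.617 (1.10 ± 0.33, adjusted p = 0.124). HBE1 had 0.458 ± 0.148 against 0.112 ± 0.107 (2.05 ± 0.49, adjusted p = 0.0683). HBZ had 3.09 ± 0.713 against 2.94 ± 0.678 and HBB 49200 ± 1910 against 60600 ± 17500. Without control replicate 2, HBG1 was called higher (1.38, adjusted p = 0.0494), and HBB (-0.56, 1.8e-03), HBD (-0.59, 1.8e-03), HBA1 (-0.59, 5.21e-03), HBA2 (-0.62, 4.94e-03), HBM (-0.59, 4.33e-03) and HBQ1 (-0.52, 7.28e-03) lower. The gamma-globin share was 0.455% ± 0.175 (n = 4) against 0.276% ± 0.0374 (n = 2), a difference of 0.180 points (exact permutation p = 0.2), and 0.378 points with the read-through gene counted. Guides 1 and 2 differed in it, with 0.600% ± 0.0734 (n = 2) and 0.310% ± 0.0501 (n = 2). HBG1 was lower with guide 2 than with guide 1 (log2 difference -1.33 ± 0.19, adjusted p = 0.0285, 4 genes called between these guides). That HBG1 call was lost without guide 1 replicate 1, guide 1 replicate 2 or guide 2 replicate 1, where 1, 0 and 0 genes were called. HBG2 did not pass that test (-1.02 ± 0.17, adjusted p = 0.0638).

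The rises named were SERF1B (3.76 ± 0.69), SLC28A3 (3.31 ± 0.61), CPVL (2.02 ± 0.35), HMCN1 (1.76 ± 0.38), FAM184A (1.59 ± 0.29), LMO3 (1.52 ± 0.28), the manganese exporter SLC30A10 (1.48 ± 0.21), APPL1 (1.45 ± 0.31), the cadherin CDH6 (1.43 ± 0.20) and SLC2A14 (1.40 ± 0.26). The falls included CYP1B1 (-2.11 ± 0.44), CAVIN1 of caveolae (-1.68 ± 0.31), KLHDC8B (-1.13 ± 0.16), ACADS of fatty acid oxidation (-0.94 ± 0.20), FMNL3 (-0.93 ± 0.16), TAGLN2 (-0.90 ± 0.15), SLC50A1 (-0.88 ± 0.13), the lysosomal cystine transporter CTNS (-0.85 ± 0.16) and SLC2A4RG (-0.75 ± 0.15). Replication-dependent histones moved down (0 of 24 called singly, 24 fell adjusted over the list alone; adjusted p = 6.9e-14, adjusted p = 0.64 with an estimated correlation). Their median went from -0.37 to -0.10 without control replicate 1 (adjusted p = 0.022) and to -0.07 with the GC and length trend removed (0.019). G2 and M phase genes moved up (0 of 30, 3 rose adjusted over the list alone; adjusted p = 4.2e-04, adjusted p = 0.64 with an estimated correlation; adjusted p = 0.22 without control replicate 1). S phase genes moved up too (0 of 29, 4 rose and 2 fell adjusted over the list alone; adjusted p = 0.025, adjusted p = 0.64 with an estimated correlation), a call lost without guide 1 replicate 2 (0.085) or guide 2 replicate 1 (0.087). Cytosolic ribosomal proteins moved down (0 of 79, also 0 adjusted over the list alone; adjusted p = 0.015, adjusted p = 0.75 with an estimated correlation), turned to up without control replicate 1 (adjusted p = 0.18) and lost the call without guide 2 replicate 2 (0.18). The other 22 lists were not called (adjusted p 0.064 to 0.98), and the mitochondrially encoded list at 0.064 pointed down, but up without control replicate 1 (adjusted p = 7.4e-03). It was called down without control replicate 2 (2.6e-07) or guide 1 replicate 1 (0.035). The omission of control replicate 2 also brought calls for the alpha-like cluster (2.0e-03), interferon-stimulated (0.04), cholesterol (0.034), hypoxia (0.013) and immediate early (2.0e-03) lists, and that of guide 1 replicate 1 for the cholesterol list (0.036). The beta-like cluster was not called with all libraries and the trend left in (adjusted p = 0.30). It was called up with the GC and length trend removed (0.019) and with guide 1 alone (2.0e-03). Without control replicate 1 its median log2 fold change went from 0.28 to 0.63. Immediate early genes held the 1 single member called in any of those 22 lists, IER3, which fell (-0.74, adjusted p = 0.0482). Median, mean and test differed in sign for the let-7, heme and iron, early erythroid, p53 and immediate early lists. With fry, histones, G2 and M phase and S phase genes (adjusted p = 0.11 each) and ribosomal proteins (0.47) were not called.

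In total 56 genes were called, 34 higher and 22 lower, with 2801 at an unadjusted p under 0.05, and DESeq2 called 492. Without control replicate 1 the count was 3, of which 1 was among the 56, and all 22 named genes lost their call. Without control replicate 2 it was 3058, and without guide 1 replicate 1, guide 2 replicate 1 or guide 2 replicate 2 it was 11, 12 or 33.

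In double knockout cells fetal and embryonic globin RNAs were at their highest of the 4 groups. HBG2 measured 2070 CPM ± 215 (n = 4) against 166 ± 26.9 (n = 2) in control, a 12.5-fold rise, and HBG1 49.9 ± 3.73 against 2.54 ± 0.617. HBE1 measured 8.97 ± 1.89 against 0.112 ± 0.107 and HBZ 31.0 ± 2.01 against 2.94 ± 0.678. The gamma-globin share was 3.69% ± 0.407 (n = 4) against 0.276% ± 0.0374 (n = 2). Adult HBB, HBD, HBA1 and HBA2 did not pass the test, with HBB at 54300 CPM ± 4030 against 60600 ± 17500. Without control replicate 2, HBB (-0.42, adjusted p = 5.12e-03) and HBD (-0.53, 1.18e-03) were called lower. HBA1 (0.54, adjusted p = 0.0156) and HBQ1 (0.57, 7.16e-03) were called higher without control replicate 1, and HBA1 (0.47, 1.35e-03) and HBA2 (0.35, 0.0214) with the GC and length trend removed.

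**Figure D2:**
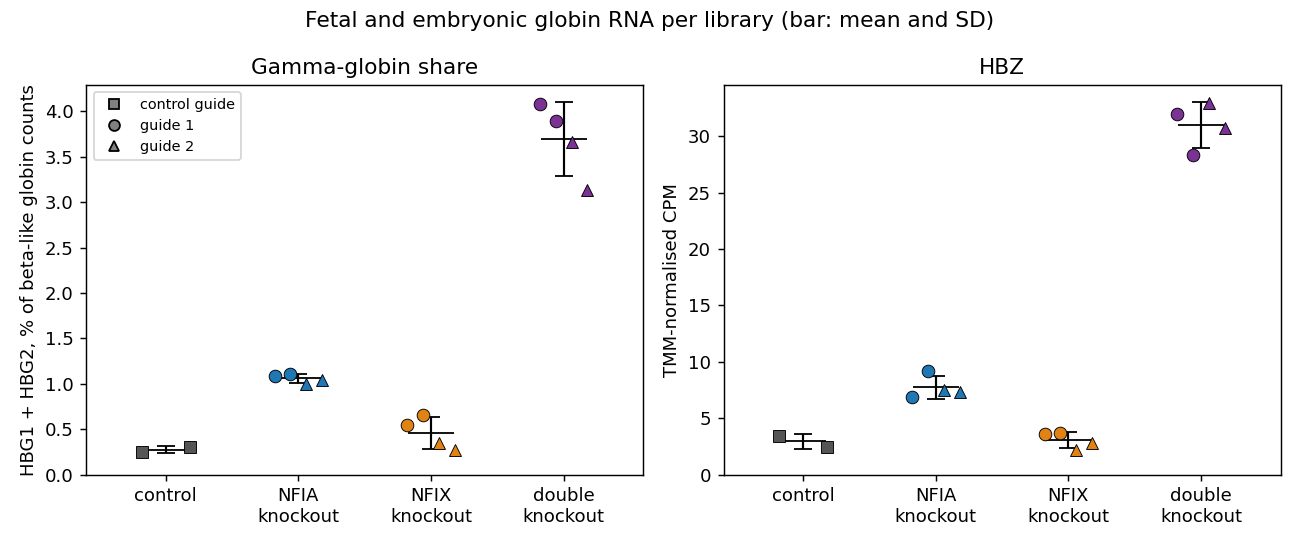
Gamma-globin share (HBG1 and HBG2 as a percentage of beta-like globin counts, left) and HBZ level (TMM-normalised CPM, right) for each library, with squares for control, circles for guide 1, triangles for guide 2, and the mean and SD per group. Double knockout libraries averaged 3.69% and 31.0 CPM against 0.276% and 2.94 CPM in control.

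In the test against control the log2 fold changes were 3.65 ± 0.30 for HBG2 (adjusted p = 2.24e-07), 4.29 ± 0.36 for HBG1 (adjusted p = 3.14e-07), 6.34 ± 0.43 for HBE1 (adjusted p = 2.42e-08), 3.40 ± 0.21 for HBZ (adjusted p = 8.93e-09), 3.94 ± 0.54 for BGLT3 (adjusted p = 4.29e-05) and 1.36 ± 0.15 for HBBP1 (adjusted p = 6.20e-06). All 6 were called in every alternative setting run. The beta-like cluster moved up (5 of 7 rose, 5 rose and 1 fell adjusted over the list alone; adjusted p = 1.6e-12), which held with an estimated correlation (adjusted p = 6.0e-03). The alpha-like cluster also moved up (adjusted p = 4.3e-03; adjusted p = 0.31 with an estimated correlation), with HBZ the 1 called member of 5, also 1 adjusted over the list alone. HBM was at -0.06 ± 0.13 but at 0.26 (adjusted p = 0.0454) with the GC and length trend removed. The share difference of 3.42 points gave an exact permutation p of 0.067, the smallest possible. It was 8.35 points with the read-through gene counted (8.93% against 0.587%) and 2.67 points from TPM.

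**Figure D3:**
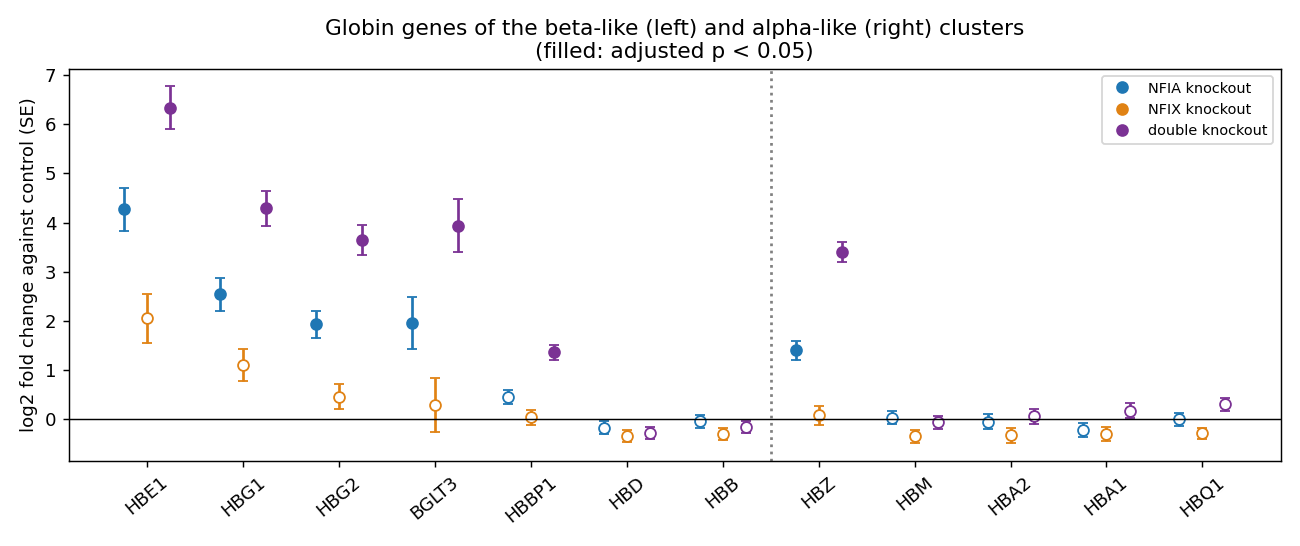
Log2 fold changes against control, with standard errors, for the globin genes of the beta-like (left) and alpha-like (right) clusters in each knockout group, filled where the adjusted p was below 0.05. HBE1, HBG1, HBG2, BGLT3, HBBP1 and HBZ were called in double knockout, and HBB, HBD, HBM, HBA2, HBA1 and HBQ1 in none of the 3 groups with all libraries and no trend removed.

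Regulators of fetal globin went both ways in double knockout, with 7 rises and 3 falls of 40 (the same numbers adjusted over the list alone) and no call of the list (adjusted p = 0.70). BCL11A, a repressor of gamma-globin (ENSG00000119866, chromosome 2, 60450520 to 60554467), fell from 46.8 CPM ± 3.1 to 31.4 ± 3.07 (-0.57 ± 0.11, adjusted p = 1.03e-03), and its partner SOX6 fell (-0.88 ± 0.19). MBD2, which takes part in silencing methylated genes (1.16 ± 0.17), and MYB (1.48 ± 0.26) rose. In NFIA knockout MBD2 was the 1 member called (0.81 ± 0.17), a call lost without control replicate 1 (adjusted p = 0.164). Of the let-7 axis, ARID3A (1.06 ± 0.10), ARID3B (1.11 ± 0.14) and IGF2BP2 (0.42 ± 0.10) rose and IGF2BP1 fell (-0.50 ± 0.15, lost without control replicate 1 at an adjusted p of 0.161), 3 rises and 1 fall of 6 (3 and 2 adjusted over the list alone; list adjusted p = 0.063).

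The 10 largest rises held CCR4 (6.80 ± 0.60), SLC28A3 (5.83 ± 0.58), CYRIA (5.11 ± 0.37), IGF2 (4.27 ± 0.35), sorbitol dehydrogenase SORD (4.11 ± 0.26), the transcription factor MYT1 (3.95 ± 0.31) and HMCN1 (3.81 ± 0.38) beside HBE1, HBG1 and BGLT3. The largest falls were in HR (-5.25 ± 0.64), JAKMIP1 (-3.98 ± 0.37), GCNT2 (-3.79 ± 0.44), SLC22A16 (-3.71 ± 0.45), ALOX5 (-3.53 ± 0.45), RAB11FIP4 (-3.40 ± 0.36), the Fc receptor FCGR2A (-3.33 ± 0.46), VSIR (-3.12 ± 0.23), PRX (-3.04 ± 0.30) and CYP1B1 (-3.02 ± 0.45), with 0.144 to 3.12 CPM left. Late erythroid maturation genes moved up (14 rose and 4 fell of 36, the same adjusted over the list alone; adjusted p = 0.014, adjusted p = 0.47 with an estimated correlation), with BPGM at 1.27 ± 0.14, CA2 at 0.95 ± 0.13 and BNIP3L, which clears mitochondria, at 0.87 ± 0.12. That call was lost in the guide-level fit (adjusted p = 0.076), with guide 1 alone (0.17) and without control replicate 2 (0.27). The p53 targets moved up (8 rose and 1 fell of 24, 9 and 1 adjusted over the list alone; adjusted p = 4.3e-03, adjusted p = 0.27 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 2.11 ± 0.18 and ZMAT3 at 2.10 ± 0.27. Replication-dependent histones moved down, and all 24 tested fell (24 adjusted over the list alone; adjusted p = 9.4e-20, adjusted p = 0.27 with an estimated correlation), with H1-3 at -1.05 ± 0.12. Their median went from -0.71 to -0.40 without control replicate 1 (adjusted p = 7.9e-12). Mitochondrially encoded mRNAs moved down (4 of 13 fell, 6 adjusted over the list alone; adjusted p = 0.014, adjusted p = 0.74 with an estimated correlation), and turned to up without control replicate 1 (adjusted p = 0.90).

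The other 20 lists tested were not called (adjusted p 0.063 to 0.99), though single members passed. Red cell membrane genes included 7 rises, such as XK (0.90 ± 0.11) and ERMAP (0.73 ± 0.09), and 6 falls, such as the Kidd antigen urea transporter SLC14A1 (-2.08 ± 0.28) and the water channel AQP1 (-0.91 ± 0.12), of 34 (7 and 6 adjusted over the list alone). Heme and iron genes included 7 rises, such as HMOX1 (0.99 ± 0.18), and 3 falls of 26 (8 and 3 adjusted over the list alone). Erythroid transcription factors had 6 rises and 2 falls of 23 (6 and 4 adjusted over the list alone), KLF13 at -0.71 ± 0.11, and adult-stage markers 1 rise and 2 falls of 5 (1 and 3 adjusted over the list alone). The adult-stage list was called down in the guide-level fit (adjusted p = 1.5e-03), with guide 1 (1.0e-03) or guide 2 (9.5e-03) alone and with fry (1.2e-03). Fry also called the let-7 (1.9e-04), heme and iron (3.5e-04), early erythroid (0.022) and megakaryocyte (3.5e-04) lists up and the mast cell list (0.026) down. The call of the mitochondrially encoded list was lost with fry (0.17). With the GC and length trend removed the let-7 (0.03), heme and iron (0.03) and megakaryocyte (0.045) lists were called up and G2 and M phase genes down (1.4e-03). Early erythroid genes had 2 rises, MYC (1.43 ± 0.15) and MYB, and 2 falls, KIT and CDK6 (-1.41 ± 0.25), of 12 (3 and 2 adjusted over the list alone). Rises and falls were 2 and 0 of 6 for megakaryocyte genes, 0 and 0 of 7 for neutrophil and monocyte genes and 0 and 3 of 6 for mast cell genes, each unchanged adjusted over the list alone. They were 3 and 4 of 29 for S phase genes (3 and 4 adjusted over the list alone) and 0 and 6 of 30 for G2 and M phase genes (0 and 7 adjusted over the list alone). They were 5 and 2 of 21 for the integrated stress response (6 and 2 adjusted over the list alone), 1 and 2 of 21 for interferon-stimulated genes (1 and 2 adjusted over the list alone), 4 and 4 of 24 for cholesterol synthesis (4 and 6 adjusted over the list alone) and 2 and 0 of 23 for hypoxia and glycolysis (2 and 0 adjusted over the list alone). They were 2 and 3 of 14 for heat shock proteins, 1 and 3 of 15 for immediate early genes, 1 and 1 of 5 for nuclear RNAs, each unchanged adjusted over the list alone, and 7 and 2 of 79 for ribosomal proteins (6 and 1 adjusted over the list alone). Median, mean and test differed in sign in this comparison for S phase, cholesterol synthesis, immediate early and ribosomal protein lists, none of them called. With control replicate 1 left out, the let-7 (adjusted p = 0.013), heme and iron (6.9e-03), early erythroid (0.023), integrated stress response (0.036), hypoxia (3.9e-03) and ribosomal protein (4.8e-03) lists were called up. G2 and M phase genes were then called down (3.8e-05). With control replicate 2 left out, ribosomal proteins were called down (0.045), and the calls of the alpha-like cluster (0.28), late maturation (0.27) and p53 (0.17) lists were lost.

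Double knockout changed 2938 genes against control, 1517 higher and 1421 lower. The count was 1747 without control replicate 1, and 1390 of the 2938 kept their call. Of the 103 named genes called here, 58 were called in every alternative and 26 lost the call in the same direction without control replicate 1, among them KIT, FOSB and DUSP1. TPSAB1 lost its call there too and changed direction (0.19, adjusted p = 0.953).

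**Figure D4:**
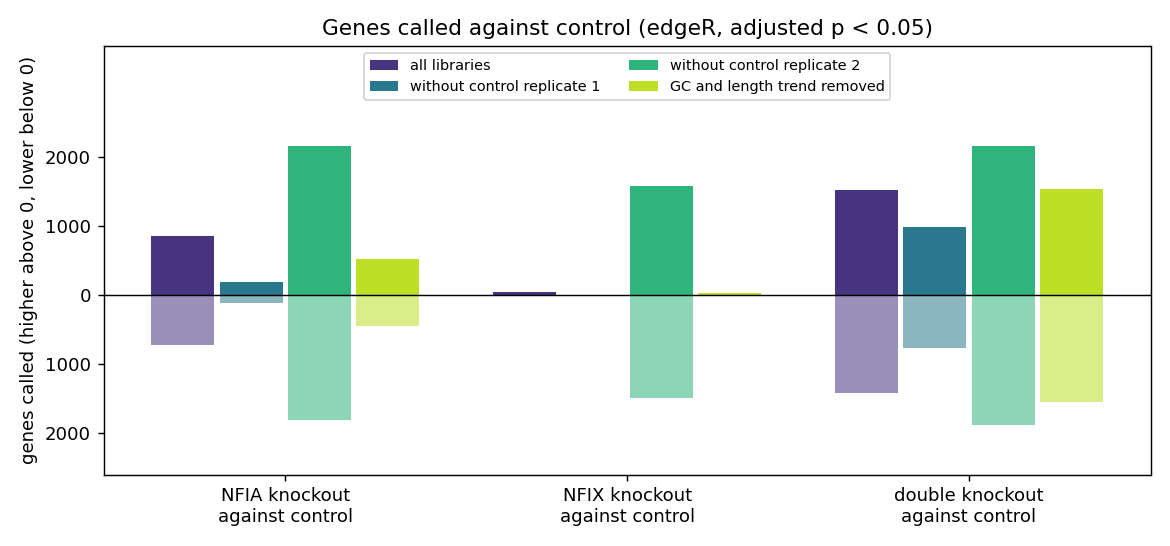
Genes called higher (above 0) and lower (below 0) against control in each knockout group, with all libraries, without either control library and with the GC and length trend removed. With all libraries 1576, 56 and 2938 genes were called, and without control replicate 1 the counts were 304, 3 and 1747.

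Adding NFIX guides to NFIA guides went with more fetal and embryonic globin RNA. The contrast gives the control libraries no weight, though they enter the filter, the normalisation and the estimate of spread. HBG2 was higher in double knockout than in NFIA knockout, 2070 CPM ± 215 against 630 ± 49.9 (n = 4 each; log2 fold change 1.72 ± 0.21, adjusted p = 8.80e-05), as were HBG1 (1.75 ± 0.23, adjusted p = 2.48e-04), HBE1 (2.07 ± 0.22, adjusted p = 4.85e-05), HBZ (2.00 ± 0.14, adjusted p = 5.03e-07) and BGLT3 (1.98 ± 0.35, adjusted p = 3.17e-03). The gamma-globin share was 2.63 points higher (exact permutation p = 0.029, the smallest of 70 splits). NFIA itself did not pass the test between these groups (-0.06 ± 0.17, adjusted p = 0.917), nor did NFIX (-0.19 ± 0.08, adjusted p = 0.169) or HBB (-0.11 ± 0.11, adjusted p = 0.644). CCR4 (2.84 ± 0.31) and BMS1P4-AGAP5 (4.78 ± 0.86), a read-through transcript that shares sequence with related genes, were also higher. HR (-2.41 ± 0.62), RAB11FIP4 (-1.94 ± 0.33), GCNT2 (-1.88 ± 0.39), SLC22A16 (-1.76 ± 0.40) and JAKMIP1 (-1.67 ± 0.35) were lower. The HR call was lost without NFIA knockout guide 2 replicate 1 (adjusted p = 0.112) or 2 (0.0953) or double knockout guide 1 replicate 1 (0.113) or 2 (0.0811). The SLC22A16 call was lost without the same NFIA knockout libraries (0.0666 and 0.0694) or double knockout guide 1 replicate 1 (0.066). Of the 13 named genes called, 6 were called in every alternative. Altogether 708 genes were called, 417 higher and 291 lower. Without double knockout guide 1 replicate 1 or 2 the count was 239 or 445, and without NFIA knockout guide 2 replicate 1 or 2 it was 333 or 317.

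Adding NFIA guides to NFIX guides went with a larger shift. HBG2 was 2070 CPM ± 215 in double knockout against 227 ± 92.9 in NFIX knockout (n = 4 each; 3.19 ± 0.22, adjusted p = 2.74e-08), and HBG1 (3.19 ± 0.25), HBE1 (4.29 ± 0.26), HBZ (3.32 ± 0.15), BGLT3 (3.66 ± 0.39), CCR4 (4.43 ± 0.35), CYRIA (4.38 ± 0.25) and the exocytosis gene STX1A (3.66 ± 0.18) were higher. HBA1 (0.48 ± 0.12, adjusted p = 0.0118), HBA2 (0.39 ± 0.12, adjusted p = 0.0426) and HBQ1 (0.59 ± 0.10) were higher by less. The HBA2 call was lost without any 1 of 6 of the 8 libraries, NFIX knockout guide 1 replicate 1 (adjusted p = 0.0852), guide 2 replicate 1 (0.135) and guide 2 replicate 2 (0.0715) and double knockout guide 1 replicate 1 (0.0944), guide 2 replicate 1 (0.132) and guide 2 replicate 2 (0.0764). HBB did not pass the test (0.14 ± 0.11, adjusted p = 0.425). HR (-3.84 ± 0.60), FCGR2A (-3.03 ± 0.42), SLC22A16 (-3.0 ± 0.41), JAKMIP1 (-2.84 ± 0.34) and RAB11FIP4 (-2.40 ± 0.33) were lower. The gamma-globin share was 3.24 points higher (exact permutation p = 0.029, the smallest possible), and 2277 genes were called, 1267 higher and 1010 lower.

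The single knockouts differed directly in their globin RNAs. HBG2 (-1.47 ± 0.20, adjusted p = 8.33e-04), HBG1 (-1.44 ± 0.24, adjusted p = 4.24e-03), HBE1 (-2.22 ± 0.26, adjusted p = 1.72e-04) and HBZ (-1.32 ± 0.15, adjusted p = 1.44e-04) were lower in NFIX than in NFIA knockout, and the gamma-globin share differed by -0.606 points (exact permutation p = 0.029, the smallest possible). CYRIA (-2.51 ± 0.25), IGF2 (-2.26 ± 0.24), GNG2 (-1.81 ± 0.19) and STX1A (-1.75 ± 0.18) were also lower in NFIX knockout. BMS1P4-AGAP5 (4.60 ± 0.86), the integrin ITGA5 (2.25 ± 0.26), CYP4F12 (1.63 ± 0.39) and FCGR2A (1.54 ± 0.38) were higher. With 1 library left out the CYP4F12 call was lost in 8 of 8 cases (adjusted p 0.0632 to 0.15) and the FCGR2A call in 7 of 8 (0.0693 to 0.196 in those). The BMS1P4-AGAP5 call was lost without NFIA knockout guide 1 replicate 1 (0.0546), and of the 16 named genes called 6 were called in every alternative. In total 207 genes were called, 74 higher and 133 lower in NFIX knockout. Leaving out 1 library gave 62 to 179, with counts over 1.5 times smaller without NFIA knockout guide 1 replicate 1 (62), guide 1 replicate 2 (94) or guide 2 replicate 1 (125), or NFIX knockout guide 1 replicate 2 (115), guide 2 replicate 1 (104) or guide 2 replicate 2 (86).

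Genes called in both single knockouts were counted, though both comparisons used the same 2 controls. Of the 1576 and 56 called genes 49 were called in both in 1 direction, 31 higher and 18 lower, and 0 in opposite directions (3 for independent lists, which the shared controls rule out as a fair reference). SLC28A3, HMCN1, SERF1B and CAVIN1 were among the genes named in both. The controls are 2 libraries and cannot be split between the comparisons. Across 14498 genes the fold changes correlated at 0.67, where the simulations gave 0.71 from the shared controls alone, with a covariance of 0.232 against 0.178 and the same sign in 81.8% of genes against 73.4%. The shared count was 3 without control replicate 1, and without control replicate 2 it was 2593. NFIA and double knockout shared 1285 called genes in 1 direction, with a correlation of 0.77 against 0.70 in the simulations, a covariance of 0.378 against 0.176 and the same sign in 80.7% of genes against 73.2%. NFIX and double knockout shared 53, with 1 opposite, a correlation of 0.58 against 0.70, a covariance of 0.253 against 0.177 and the same sign in 75.2% against 73.4%. The simulations shared 0 called genes in each pair, where unchanged groups should give few calls to share, so these counts were not weighed against that 0. They gave the controls the same spread as the other groups. The real control pair differed most, with an SD of log2 ratios of 0.493 against at most 0.374 in the other pairs. The simulated values can therefore understate what the shared controls alone give, and no conclusion is drawn from the differences.

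The 2 guides of a group agreed in direction for the genes called against control, in 1571 of 1571, 56 of 56 and 2902 of 2902 genes tested with each guide alone, where both guides share the controls and the genes were chosen for the group's change. Between guides 1, 4 and 13 genes were called in NFIA, NFIX and double knockout. SLC22A16 was higher with guide 2 in NFIA knockout (1.5 ± 0.14, adjusted p = 2.37e-04, the 1 gene called) and in double knockout (1.92 ± 0.16, adjusted p = 6.21e-05), where IFIT1B (1.77 ± 0.19) and SLC14A1 (1.28 ± 0.14) were also higher. With 1 NFIX knockout library left out, 1 gene was called between NFIX guides without guide 1 replicate 1, and 0 without guide 1 replicate 2 or guide 2 replicate 1 (edgeR, with 491 and 468 at an unadjusted p under 0.05). The guide left with 1 library is assumed there to vary like the other groups. In double knockout 3 or 4 were called without any 1 of its libraries.

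The double knockout effect differed from the sum of both single effects in 8 genes, 7 with a higher value and 1 with a lower. HBZ exceeded the sum by 1.92 ± 0.24 on the log2 scale (adjusted p = 1.26e-03), STX1A by 1.98 ± 0.29 (adjusted p = 7.37e-03), the actin-bundling gene ESPN by 1.43 ± 0.23 (adjusted p = 0.0132), the P-selectin ligand SELPLG by 1.18 ± 0.17 (adjusted p = 7.37e-03) and the transcription factor ELK1 by 0.94 ± 0.16 (adjusted p = 0.0313). ESPN measured 37.9 CPM in control, 25.6 in NFIA knockout, 22.9 in NFIX knockout and 41.6 in double knockout. Its term thus came with lower means in both single knockouts and a double knockout mean near control. ELK1 measured 30.7, 28.7, 25.8 and 46.2 CPM in the same order. HBG2 did not pass the non-additivity test (1.26 ± 0.31, adjusted p = 0.0749), nor did HBG1 (0.65 ± 0.40, adjusted p = 0.400). HBG2 was called without control replicate 2 (1.42, adjusted p = 0.0133) or NFIX knockout guide 1 replicate 2 (1.5, adjusted p = 0.0405). Without control replicate 1 the count was 4 and of the 5 named genes HBZ alone remained called (adjusted p = 0.038). Without control replicate 2 the count was 2759, and without NFIX knockout guide 1 replicate 2 it was 16.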

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

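The tests on globin depletion, shared reads, wrong labels and the GC trend of the globin and histone genes were chosen after the results were seen, as were the bounds for wrong labels. The bounds for the histone genes were tightened after their values were seen, which left NFIX knockout open. The splits of the libraries were planned. The bound for the control pair was written before its result was seen, but the trend removal it uses was added after seeing the data.

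HBA1 was the adult alpha-globin gene with 1 library far from the other 3 in 2 groups. In NFIA knockout 1 library had 27240 CPM against 34970 to 36160 in the others (gap over range 0.867), and in double knockout 1 had 45300 against 43370 to 43630 (0.865). These were 2 of 75 groups tested, and chance gives about 1 in 20.

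In 8 genes the double knockout effect differed from the sum of the single effects. On the log2 scale the difference was 1.98 for STX1A, 1.18 for SELPLG, 0.94 for ELK1, 1.92 for HBZ and 1.43 for ESPN. UPK1A-AS1 (1.81), LINC02972 (0.82) and ENSG00000267059 (-10.81) lay outside the naming rule and were chosen after their values were seen. STX1A had 1.13 CPM in control, 3.63 in NFIA, 1.08 in NFIX and 13.7 in double knockout. ENSG00000267059 had 0 CPM in both controls and 7.7, 5.77 and 10.7 CPM in the knockout groups, so its fitted value is no bound. Without control replicate 1 HBZ (adjusted p = 0.038), LINC02972 (0.038) and ENSG00000267059 (0.038) were still called, and STX1A (0.24), SELPLG (0.12), ELK1 (0.33), ESPN (0.21) and UPK1A-AS1 (0.13) were not.

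The first pattern weighed was the difference between the 2 control libraries, whose log2 ratios over protein-coding genes had an SD of 0.493, the highest of the 7 replicate pairs. With the GC and length trend removed the SD was 0.392 against 0.347 in the next pair, which argues against the trend as the whole cause. A knockout library under a control label was argued against by control replicate 1 lying at least 8.4 group SDs from each knockout group in a targeted gene or the gamma-globin share (0.249 percent against 3.14 to 4.08 in double knockout and 0.998 to 1.11 in NFIA knockout, and NFIX at 242 CPM against 145 to 165 in NFIX knockout). For NFIX knockout this rests on NFIX alone, with the GC and length trend left in. The gamma-globin share of control replicate 1 lay 1.2 SDs below the mean of that group. No biological explanation was tested.

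The second pattern was the rise of HBG1, HBG2, HBE1 and HBZ in double knockout. A common efficiency of globin depletion was argued against by the adult genes, whose largest log2 fold change was 0.17 (SE 0.15). It was 0.54 for HBA1 without control replicate 1 (adjusted p = 0.0156), still below the 3.65 of HBG2, so a smaller common part stays open. Depletion that differs between globin genes and between libraries was not tested. Reads moved between HBG1, HBG2 and their read-through gene were argued against by the sum of the 3 genes, at a log2 ratio of 3.9, and the GC trend by HBG2 at 3.75 with the trend removed. A change in transcription after loss of both factors is a hypothesis that may explain the rise. It was not tested, and protein loss was not measured.

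The third pattern was lower RNA of replication-dependent histones. With the GC and length trend removed the list's median log2 fold change went from -0.35 to -0.03 in NFIA knockout (adjusted p = 0.35), so the trend may account for it there. In NFIX knockout it went from -0.37 to -0.07 (adjusted p = 0.019), smaller but still called at the preset correlation, and the trend as the whole cause stays open. In double knockout it went from -0.71 to -0.44 (adjusted p = 5.5e-12; -0.40 without control replicate 1), which argues against the trend as the whole cause. With the trend left in, these 2 calls were lost with an estimated correlation (adjusted p = 0.64 and 0.27). In double knockout with the trend removed, G2 and M phase genes were called down (median -0.21, adjusted p = 1.4e-03). S phase genes were not called there (adjusted p = 0.93). A change in cell division, a biological explanation, was not tested as a cause.

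Splits of the 8 libraries of 2 knockout groups were counted for each comparison between knockouts. In each, 1 of 35 splits, the real one, called as many genes, which is the smallest share this design allows. The real splits called 708 genes between double and NFIA knockout, 2277 between double and NFIX knockout and 207 between the single knockouts. At most 1 gene was called in any other split. A mixed split adds the group difference to the spread within its groups, and each group holds 2 guides. The size of the gap to the other splits is therefore no added evidence. The rank of the real split argues against chance only if libraries are taken as independent, which 2 guides per group do not assure. It does not exclude chance.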

How the results depend on the processing

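The GC and length offset, alone and with the replicate block, the removal of small structural RNAs, the omission of 2 libraries together and the read-through share were chosen after seeing the data; the other alternatives were planned. The 2 libraries are control replicate 1 and double knockout guide 1 replicate 2. Where a cause is not given, the cause was not tested. The double knockout calls of HBG2, HBG1, HBE1, HBZ, BGLT3 and HBBP1 held in all 19 alternatives each. With the replicate block 1527 of 1576, 43 of 56 and 2860 of 2938 genes called against control in NFIA, NFIX and double knockout kept their call, and 17 of 22 named genes in NFIX knockout did. No setting shifted the median of all genes by over 0.1.

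NFIA knockout against control (1576 genes) gave 878 with only the groups compared, 403 and 188 with guide 1 or 2 alone (fewer libraries), 2619 with limma-voom, 961 with the offset, 1047 with the offset and the replicate block, 394 without the 2 libraries and 304 to 3960 with 1 library left out. NFIX knockout (56) gave 9 with only the groups compared, 492 with DESeq2, 559 without a filter, 7 and 6 with guide 1 or 2, 515 with limma-voom, 5 without the 2 libraries and 3 to 3058 with 1 left out. Double knockout (2938) gave 1868 with only the groups compared, 1433 and 1292 with guide 1 or 2, 1745 without the 2 libraries and 1747 to 4042 with 1 left out.

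Double against NFIA knockout (708) gave 1247 with only the groups compared, 1173 with DESeq2, 1202 without a filter, 69 and 37 with guide 1 or 2, 1411 with limma-voom, 1384 with the offset, 1517 with the offset and the replicate block, and 239 to 611 with 1 left out. Double against NFIX knockout (2277) gave 608 and 353 with guide 1 or 2 and 1529 to 2046 with 1 left out. NFIX against NFIA knockout (207) gave 378 with only the groups compared, 443 with DESeq2, 543 without a filter, 20 and 21 with guide 1 or 2, 458 with limma-voom, 414 with the offset, 504 with the offset and the replicate block, 445 without the 2 libraries and 62 to 179 with 1 left out. Non-additivity (8) gave 18 in the guide-level fit, 736 with DESeq2, 769 without a filter, 0 and 5 with guide 1 or 2, 722 with limma-voom, 19 with the offset, 35 with the offset and the replicate block, 5 without the 2 libraries and 4 to 2759 with 1 left out.

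Between guides, NFIA knockout (1) gave 2 with the replicate block, 24 without a filter, 2 with the offset, 4 with DESeq2 and 1 to 1 with 1 left out. NFIX knockout (4) gave 47 without a filter, 7 with the offset, 1 with only the groups compared, 10 with DESeq2 and 0 to 3 with 1 left out, and double knockout (13) gave 142, 68 with the offset, 76 with DESeq2 and 3 to 4 with 1 left out. Gene lists called were 6 in NFIA knockout (0 with an estimated correlation, 4 to 8 with 1 left out) and 4 in NFIX knockout (0 with an estimated correlation, 0 with fry, 7 with guide 2, 7 with the offset, 7 with the offset and the replicate block, 3 to 10 with 1 left out). Double knockout had 6 lists (1 with an estimated correlation, 11 with fry, 10 with the offset, 10 without the 2 libraries, 4 to 12 with 1 left out). The shared response (49) gave 418 with DESeq2, 469 without a filter, 5 without the 2 libraries and 3 to 2593 with 1 control left out. The gamma-globin share difference was 0.644 points from TPM and 1.88 with the read-through gene in NFIA knockout (0.759 to 0.812 with 1 left out). It was 0.378 with the read-through gene in NFIX knockout (0.114 to 0.24), and 2.67 from TPM and 8.35 with the read-through gene in double knockout (3.29 to 3.6).

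Of 26 lists, called or not, 6 in NFIA, 9 in NFIX and 7 in double knockout pointed the other way without control replicate 1. Those called with all libraries or under the alternative are given here. The ribosomal protein list turned in NFIA knockout without control replicate 1 (adjusted p = 0.77) and without the 2 libraries (0.72), and in NFIX knockout (0.18 and 0.11). In double knockout it turned without control replicate 2 (0.045). With 1 library left out its adjusted p ran from 7.2e-07 to 0.77 in NFIA, 6.1e-07 to 0.18 in NFIX and 0.0048 to 0.85 in double knockout. The mitochondrially encoded list turned in NFIX knockout without control replicate 1 (7.4e-03) and without the 2 libraries (4.2e-03) and in double knockout (0.9 and 0.72). With 1 library left out its adjusted p ran from 2.6e-07 to 0.16 in NFIX and 9e-09 to 0.9 in double knockout. With the offset, alone and with the replicate block, HBQ1 in NFIA knockout was at 0.36 and 0.36 and HBM in double knockout at 0.26 and 0.26. In double knockout TPSAB1 was at 0.19 without control replicate 1, -3.74 without control replicate 2 and 0.58 without the 2 libraries, where DUSP1 was at 0 and MT-ND4L at 0.09.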

Other observations

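ENSG00000283029, singled out after its values were seen, had 27600 and 29600 CPM in the 2 controls, 0.105 to 5640 CPM in NFIX knockout and at most 66.4 CPM in the other 8 libraries. Its sum with RN7SL1 and RN7SL2, in CPM of total counts without TMM, was 229999 and 179295 in the controls. That sum was 188365 to 204312 in NFIA, 185088 to 197637 in NFIX and 202077 to 237890 in double knockout. The sum thus did not show the fall of the single gene. Whether reads moved among these genes was not tested.

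The tests below were planned and their bounds, 80% and 60%, were written before the results were seen. A hypothesis was that loss of NFIA moves genes the same way with and without NFIX guides. Of the 2277 genes called between double and NFIX knockout, 1783 (78.3%) had the same sign in NFIA knockout against control, which shares no library with that comparison, against 58.5% of all genes. The value was 88.3% without control replicate 1, 69.4% without control replicate 2 and 87.7% with the GC and length trend removed. With all libraries it lay between the bounds, so the hypothesis stays undecided by this test. Outside the planned test, genes called in both comparisons were counted. Of these, 742 went in the same direction and 8 in opposite directions.

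A second hypothesis was that NFIX guides move genes the same way with and without NFIA guides. Of the 708 genes called between double and NFIA knockout, 468 (66.1%) had the same sign in NFIX knockout against control, against 49.5% of all genes. The value was 77.8% without control replicate 1, 56.8% without control replicate 2 and 75.4% with the trend removed. This hypothesis stays undecided by this test as well. Of the genes called in both comparisons, 21 went in the same direction and 1 in opposite directions.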
